A study of Mus musculus with 9 samples.

How the data were processed

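Per the labels, each library was made from the lung of a mouse of a strain that carries the autophagy marker LC3 fused to green fluorescent protein. The 9 samples fall into 3 groups of 3: sham irradiation, whole-brain X-irradiation with a single 10 Gy exposure at 2 Gy per min, and 3 such exposures given weekly. The labels give neither the time from the last exposure to tissue collection nor the sex of the mice. They give no schedule for the sham group, so any differences between groups in age, handling or time on study cannot be told apart from exposure. The labels number the libraries within a group, and nothing states that each came from a separate animal. The p-values therefore measure the spread between these samples. Per the labels' protocols, lungs were frozen on dry ice, RNA was isolated with Trizol, ribosomal RNA was depleted from 1 µg, and stranded total RNA libraries were sequenced for 150 cycles on an Illumina HiSeq. Per the submitters' processing notes, reads were handled with cutadapt 1.9.3 and HISAT2 2.0.4 on the mouse build mm10. The program that estimated expression and its annotation are not given in the sources used here.

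The deposited table held 22564 protein-coding genes with 2 values per library, which per the file headers are FPKM and counts. The authors' estimated counts were not whole. Within each library they were multiples of 1 step between 0.854 and 1.19, and after division by that step 91.6 to 92.9% of all values and 95.0 to 96.1% of low values lay within 0.1 of a whole number. The deposited counts were therefore read as estimated fragment counts multiplied by 1 factor per library. They were divided by the library's step and rounded to whole numbers before testing. Fragments per library obtained in this way ranged from 4987856 to 7381021. At these depths counting error is small for abundant genes and large for genes with fewer than 10, and floors given in the text cover counting error only. Of all genes, 4897 were 0 in every library, 83 symbols were repeated, and 5877 genes shared a locus with another gene, so that values of overlapping genes and near-identical copies are uncertain. Coordinates are those of the GENCODE M21 annotation of GRCm38, the same build as mm10, counted from 1. Of 21839 genes with an entry there, 21813 overlapped the deposited locus.

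The design fixed before the data were examined listed limma for FPKM and edgeR for counts. Because the table held counts as well, edgeR was the main test and limma on log2(FPKM + 1) an alternative. Counts were filtered with filterByExpr, which left 14074 genes, and normalized with TMM. All 9 libraries entered 1 quasi-likelihood fit with a mean per group (glmQLFit and glmQLFTest), with 6 residual degrees of freedom and a common biological coefficient of variation of 0.316. The contrasts were a single exposure against sham, 3 weekly exposures against sham, 3 weekly exposures against a single exposure, the mean of both irradiated groups against sham, and an F-test of any difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Normalized counts are CPM computed with TMM factors. Log2 fold changes are given with a standard error (SE), taken as the absolute change over the square root of the F statistic of its quasi-likelihood test. The n beside it counts libraries. This SE treats the 3 sham libraries as independent and may be too small if they are not. Genes at an unadjusted p under 0.05 and at least 2-fold change were counted beside the number of genes that chance gives, and were not called.

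Before the data were examined, 52 gene lists were fixed for processes, lung cell types, neighbouring tissues and RNA quality, and 49 had at least 5 measured genes. The lists of mast cells and basophils, of eosinophils, and of oesophagus, tracheal cartilage or thyroid were too small, with 3, 3 and 2 measured genes. Lists were tested with limma's camera, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the lists of a contrast. Each test was repeated with an estimated correlation and with fry. The p-value of fry tests whether the genes of a list move, on balance, one way, and its mixed p-value whether they change in either direction. Neither compares the list with other genes.

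The genes named were also chosen by a rule fixed before the data were examined. Per contrast and direction, the rule took 10 called genes with non-overlapping groups and at least 2-fold change. Where fewer than 5 qualified it took the 5 with the smallest unadjusted p among genes with non-overlapping groups, as not called. It added the 4 members with the smallest p of each called list, and 15 genes in every contrast, of which 13 were tested. Genes outside this rule are named as such.

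The pipeline was tested on simulated counts with 200 changed genes at the real depths. In the simulation of a single exposure against sham, edgeR recovered 9 of 67 genes changed 2-fold, 53 of 67 changed 4-fold and 58 of 66 changed 8-fold, and called 8 unchanged genes. For 3 weekly exposures against sham the corresponding numbers were 17 of 67, 55 of 67 and 62 of 66, with 6 unchanged genes called. For the contrast of the irradiated groups they were 9 of 67, 50 of 67 and 57 of 66, with 6. DESeq2 called 35, 47 and 34 unchanged genes in the same simulations. Camera called the 1 lowered list in each simulation and no other list. Fry called it in each as well, with 2 other lists in the simulation of a single exposure. Genes and libraries were drawn independently of each other. The simulations therefore do not show how often camera calls lists of correlated genes, or what a sham library that shares reads does to the calls. With an estimated correlation the adjusted p of the lowered list was 0.134, 0.0115 and 0.0253.

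Alternatives fixed before the data were examined were DESeq2 and its size factors, no filter or a mean FPKM of at least 1, a replicate block, fits of only the 6 samples compared, limma on FPKM with pseudocounts of 0.5 or 0.1, other normalizations or array weights, and leaving out each library. Robust moderation, limma voom, counts as deposited, limma on log2(FPKM + 1), and further fits without sham library 1 or without pairs of irradiated libraries were added after the data had been seen. Sham library 1 lay closer to the average of the other sham libraries than separately drawn reads would, as described in the report. No 2 sham libraries were identical, so it was kept as a library in the designed fit. Values without it stand beside the counts of genes and some of the list tests, but not beside the log2 change of each gene. They are also missing for the numbers of genes called over a list alone, which were not adjusted over lists or contrasts. Sham library 1 is not shown to be an independent animal, and therefore no mean and SD over the 3 sham libraries is given. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.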

Results

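Transcripts of protein-coding genes were measured by ribosomal RNA-depleted RNA sequencing in 9 lung libraries of LC3 reporter mice, 3 after sham treatment, 3 after a single whole-brain exposure to 10 Gy and 3 after weekly exposures to 10 Gy over 3 weeks. The series asks about bystander effects in the lung, an organ outside the irradiated field. Fragments per library were 6149153, 5270625 and 4987856 in the sham group, 6909859, 5747281 and 6415690 after a single exposure and 5631297, 7381021 and 6153105 after 3 exposures. Mitochondrially encoded transcripts made up 7.16% of the fragments in library 1 of the single exposure and 5.82% in library 1 of the 3 exposures, against 1.73 to 3.10% in the other libraries. Scgb1a1, the secretoglobin of club cells, made up 2.24 to 3.95%. The first principal component held 37.2% of the variance and separated library 1 of the single exposure. The second held 17.1%, with the sham libraries at 22.02 to 40.1 and the irradiated libraries at -42.8 to -1.62.

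The libraries differed in tissue other than lung parenchyma. Library 1 of the single exposure held 5176 CPM of Myh6, the cardiac myosin heavy chain (chromosome 14, 54941921 to 54966927), against 181 to 243 CPM in sham and 10.3 and 201 CPM in its group mates. In the same library the medians of the alveolar type 1 list (-2.04) and the endothelial list (-1.98) lay below the sham level, and those of smooth muscle (1.79) and adipocytes (2.39) above it, in log2 units. Sham library 1 held 4995 fragments of Myh4, the fast skeletal myosin heavy chain, which had 0 fragments in the other 8 libraries.

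For most genes, sham library 1 lay midway between the other sham libraries, with exceptions such as skeletal muscle genes and Lars2, which had 1616 fragments against 131 and 102. It was between them in 71.7% of genes, against 12.8% and 15.5% for sham libraries 3 and 2 and 24.5 to 43.4% for the irradiated libraries within their groups. Over 10696 genes, its median squared deviation from the equal mix of sham libraries 2 and 3 was 0.170 times the counting variance, below the chi-square median of 0.455 for separately drawn reads. Simulated separate reads gave 0.439 to 0.482, or 0.277 to 0.305 with sham libraries 2 and 3 taken as free of counting error, and reads drawn from those libraries gave 0.112. The sham values are therefore not shown to be 3 independent measurements, and the spread of the sham group may be too small. Without sham library 1, edgeR found 763 genes at an unadjusted p under 0.05 for the single exposure (5.34% of those tested) and 492 for the 3 exposures (3.44%), against 1693 (12.03%) and 1112 (7.90%) with it. Leaving out another sham library lowered both counts as well, to 1263 and 889 without sham library 2 and to 930 and 672 without sham library 3. Part of the fall may therefore come from having fewer sham libraries.

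**Figure D1:**
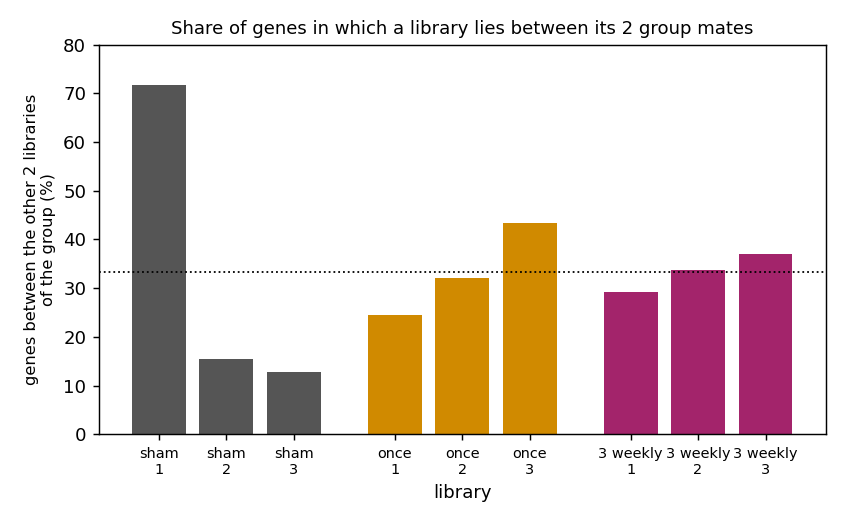
Share of genes, in percent, in which each library lay between the other 2 libraries of its group, with 1 bar per library and a dotted line at the share of equivalent libraries. Sham library 1 stood at 71.7%, and every other library lay between 12.8 and 43.4%.

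The contrast of a single brain exposure with sham asks what changed in the lung after 10 Gy to the head. Immediate early genes, which encode transcription factors induced within minutes of a stimulus, fell, with a median log2 change of -0.74 and 23 of 26 measured members lower. Maff (-1.55 ± 0.25, SE, n = 3 against 3), Fosl2 (-0.94 ± 0.16), Nr4a3 (-1.81 ± 0.39) and Csrnp1 (-1.35 ± 0.30) were lower in each irradiated library than in each sham library. Genes of the type I interferon response rose, with 27 of 28 members higher and a median of 0.85. They included Irf7 (1.45 ± 0.27), the transcription factor that amplifies interferon production, Rtp4 (1.74 ± 0.31) and Ifi44 (2.46 ± 0.59). Cytosolic ribosomal protein genes fell, with 40 of 48 members lower and a median of -0.34. Differences in sample handling or RNA quality between groups were not tested, in any contrast, as a source of the falls of immediate early, ribosomal protein and heat shock genes. All 34 proliferation genes were higher, with a median of 0.95 and Tpx2, a spindle assembly factor, at 1.86 ± 0.46.

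The camera adjusted p was 1.50e-15 for immediate early genes, 5.17e-15 for interferon genes, 2.05e-15 for ribosomal proteins and 8.45e-14 for proliferation. The adjusted p was 0.482, 0.482, 0.482 and 0.493 with an estimated correlation. Adjusted over the list alone, 10 immediate early genes and 19 ribosomal protein genes were called lower and 8 interferon genes higher, with 0 proliferation genes, and over all genes tested none of these was called. Glucocorticoid-responsive genes fell (median -0.72, 21 of 25 lower, adjusted p = 4.52e-09), with 6 called adjusted over the list alone, among examples Nfkbia, the inhibitor of NF-kB (-0.83 ± 0.15), and Ddit4 (-1.52 ± 0.33). Platelet and megakaryocyte genes fell (median -0.82, 21 of 23 lower, adjusted p = 1.15e-08), including Thbs1, thrombospondin 1 (-1.70 ± 0.29). Heat shock genes fell (12 of 19 lower, median -0.17, mean -0.64, adjusted p = 1.55e-06), with 6 called adjusted over the list alone. For the glucocorticoid and platelet lists the adjusted p was 0.482 with an estimated correlation, and for heat shock 0.493. The inducible heat shock genes Hspa1a (-3.19 ± 0.50) and Hspa1b (-3.94 ± 0.67) are near-identical copies, and their separate values are uncertain.

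The other 8 called lists each lost the call without 1 or more libraries. B cell genes were higher (adjusted p = 0.00345) and neutrophil (0.00968), alveolar type 1 (0.0142) and endothelial (0.0312) genes lower, and without library 1 of the single exposure, which held heart tissue transcripts, the adjusted p was 0.892, 0.113, 0.279 and 0.0803, with B cell, alveolar type 1 and endothelial genes turned in direction. The endothelial value without sham library 3 was 0.0597. NK cell and cytotoxic genes (0.0312) and monocyte genes (0.0201) were higher, but without library 2 of the single exposure they stood at 0.361, turned in direction, and 0.209, and NK genes without sham library 2 stood at 0.111. Alveolar macrophage genes were higher (0.0217), with 0.186 without library 2 and 0.0965 without library 3 of the single exposure. Replication-dependent histones were higher (0.0312), with 0.221 without sham library 2 and 0.160 without library 1 of the single exposure. With an estimated correlation the adjusted p was 0.842 for the B cell, neutrophil, alveolar type 1, endothelial, NK and histone lists, 0.683 for monocytes and 0.493 for alveolar macrophages.

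Among single genes, Rps21, a protein of the small ribosomal subunit (chromosome 2, 180257377 to 180258445), had the smallest p in this contrast. It lay between 16.9 and 18.5 CPM after a single exposure and between 41.5 and 46.3 CPM in sham, a log2 change of -1.29 ± 0.14 (SE, n = 3 against 3, edgeR adjusted p = 0.0772). Crem, a cAMP-responsive transcription factor (chromosome 18, 3266048 to 3337748), was lower by the fit at -1.30 ± 0.17, and Ctgf, a matricellular growth factor (chromosome 10, 24595442 to 24598683), stood at -1.61 ± 0.25. The ribosomal genes Rpl36a and Rps20 stood at -1.04 and -0.96. The 5 genes with the smallest p among higher ones were Epb4.1l3 (1.81 ± 0.28), the interferon-induced oligoadenylate synthetase Oas3 (1.42 ± 0.23; chromosome 5, 120753098 to 120777661), Mylip (0.97), Stk24 and Pagr1b. All of these except Rps21 had an edgeR adjusted p of 0.141. Pagr1b had 0 fragments in sham and 61 after a single exposure, at least 18.1-fold higher against a floor of 3 fragments over the group. It is a near-identical copy of Pagr1a, which had 109 to 190 fragments in every library, so that its value is uncertain.

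edgeR called 0 of 14074 genes in this contrast, with 1693 at an unadjusted p under 0.05 where chance gives 703.7. Of these, 487 changed at least 2-fold, 308 higher and 179 lower. DESeq2 called 198 genes, limma on log2(FPKM + 1) 5 and limma voom 0. Without sham library 1 edgeR called 0, the numbers at an unadjusted p under 0.05 and with 2-fold change as well dropped to 763 and 282, and DESeq2 called 17 genes, among them Rps21 (adjusted p = 0.00028), Crem (0.00771), Ctgf (0.00155), Maff (0.0140) and Rtp4 (0.0249). The number at an unadjusted p under 0.05 was 930 without sham library 3, and the number with 2-fold change was 758 and 928 without libraries 2 and 3 of the single exposure. The groups did not overlap in 2947 genes (20.9%), where chance gives 10% for 3 against 3 libraries and 20% for 2 against 3.

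**Figure D2:**
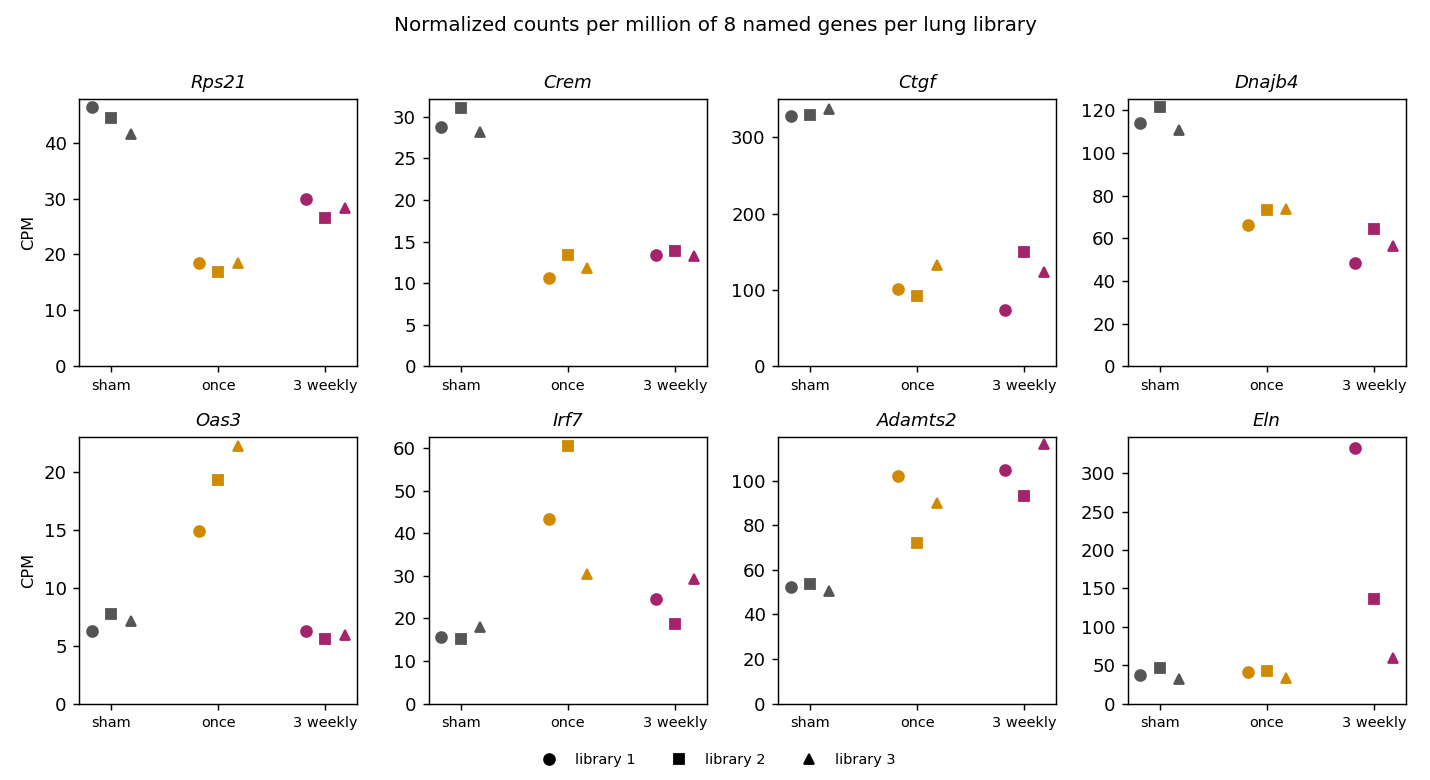
Normalized counts (CPM) of 8 named genes in each of the 9 libraries, with 1 panel per gene and 1 point per library, in the groups sham, single exposure and 3 weekly exposures. Crem lay at 28.1 to 31.1 CPM in sham and at 10.6 to 13.9 CPM in the irradiated libraries, and Eln reached 333 CPM in library 1 of the 3 exposures.

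The contrast of 3 weekly exposures with sham asks the same question for repeated doses. Library 3 of the 3 exposures, unlike the other libraries, had 0 fragments of the Y-chromosome genes looked up after the data were seen. Sex was not part of any fit. Immediate early genes fell, with a median of -1.09 and 24 of 26 members lower, among them Nr4a3 (-2.33 ± 0.40), Fosl2 (-1.10 ± 0.16) and Maff (-1.43 ± 0.25). Extracellular matrix and fibrosis genes rose, with a median of 0.57 and 27 of 30 members higher, including the gelatinase Mmp2 (0.99 ± 0.23), while Thbs1 was lower (-1.53 ± 0.28). Eln, which encodes elastin (chromosome 5, 134702593 to 134747323), stood at 333, 136 and 59.3 CPM against 31.7 to 46.4 CPM in sham. Genes of fatty acid and cholesterol synthesis rose (median 0.32, 24 of 28 higher), including the stearoyl-CoA desaturase Scd1 (2.03 ± 0.54) and the sterol reductase Dhcr7 (1.00 ± 0.22). Their median per library was 0.22, 0.20 and 0.46, and that of adipocyte genes was -1.43, -0.63 and 2.43. A share of fat tissue in the value of library 3 was not tested. Surfactant and alveolar type 2 genes rose (median 0.48, 22 of 23 higher), as did dendritic cell genes (median 0.47, 15 of 19 higher), with the actin bundler Fscn1 at 1.16 ± 0.25 and the transcription factor Irf8 at 0.71 ± 0.19.

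The camera adjusted p was 4.73e-23 for immediate early genes, 3.56e-07 for extracellular matrix, 1.37e-07 for lipid synthesis, 6.97e-06 for surfactant and 5.09e-06 for dendritic cells, and with an estimated correlation the adjusted p was 0.283, 0.283, 0.283, 0.569 and 0.347. Adjusted over the list alone, 10 immediate early genes were called lower, 13 matrix genes higher and 3 lower, 4 lipid synthesis genes higher, 0 surfactant genes, and 6 dendritic cell genes higher and 1 lower. Over all genes tested none was called. Ribosomal protein genes fell (median -0.25, 41 of 48 lower, 12 called over the list alone, adjusted p = 7.67e-11), as did platelet genes (median -0.70, 22 of 23, 2 called, 2.09e-11) such as the platelet receptor Treml1 (-2.95 ± 0.53), and glucocorticoid-responsive genes (median -0.73, 22 of 25, 3 called, 2.98e-10). For each of these 3 lists the adjusted p was 0.283 with an estimated correlation. Neutrophil genes fell (median -1.14, 15 of 18 lower, adjusted p = 7.12e-08, 0.353 with an estimated correlation), including the secreted protein Retnlg (-2.16 ± 0.70). Alveolar macrophage genes rose (median 0.69, 19 of 22, adjusted p = 0.000955, 0.283 with an estimated correlation).

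Heart muscle genes fell (median -1.93, 29 of 29 lower, adjusted p = 1.07e-09, 0.569 with an estimated correlation). Skeletal muscle genes fell (median -2.71, 13 of 13, adjusted p = 1.84e-06, 0.558 with an estimated correlation), with an adjusted p of 0.0146 without sham library 1, which held most of their fragments. Their median per library was 2.67, -0.86 and -1.31 in sham and -1.49, -2.43 and -1.50 after 3 exposures, so most of the fall came from sham library 1. Proliferation genes rose (median 0.58, 30 of 34, adjusted p = 5.15e-06, 0.569 with an estimated correlation), but without library 1 of the 3 exposures the adjusted p was 0.073. That library also carried the calls of interferon genes (median 0.22, adjusted p = 0.0129, 0.218 without it) and of MHC class II genes (median 0.46, 0.00176, 0.0611 without it). Their adjusted p was 0.726 and 0.558 with an estimated correlation. Lysosome genes (median 0.25, 0.00434) stood at 0.055 without library 3 of the 3 exposures, heat shock genes (median -0.11, 0.0109) at 0.466 without it and at 0.0577 without sham library 3, and histones (median 0.30, 0.00377) at 0.0744 without it and at 0.0903 without sham library 2. Their adjusted p was 0.528, 0.569 and 0.569 with an estimated correlation. The remaining 7 called lists had an adjusted p between 0.0383 and 0.0498 and each lost the call without 2 or more libraries. They were NRF2 antioxidant genes, the unfolded protein response, oxidative phosphorylation, plasma cells, the circadian clock, fatty acid oxidation and the TGF-beta pathway, and with an estimated correlation their adjusted p was 0.283 to 0.856.

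The single gene with the smallest p was Dnajb4, a co-chaperone of heat shock protein 70 (chromosome 3, 152178511 to 152210302), at 48.3 to 64.3 CPM against 111 to 122 CPM in sham, a log2 change of -1.03 ± 0.13 (SE, n = 3 against 3, edgeR adjusted p = 0.273). Fosl2, Crem (-1.12 ± 0.16), Ctgf (-1.52 ± 0.25) and the endothelial immediate early gene Apold1 (-3.57 ± 0.59) followed. Adamts2, the procollagen peptidase (chromosome 11, 50602084 to 50807573), stood at 93.3 to 117 CPM against 50.6 to 53.7 CPM in sham, a log2 change of 1.01 ± 0.15 (adjusted p = 0.273). The other 4 genes taken among higher ones were Sdf2l1 (1.39), the Notch target Hey2 (2.20), the collagen chaperone Serpinh1 (0.79) and the transcription factor Sox4 (1.47), with adjusted p from 0.273 to 0.357.

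edgeR called 0 genes, with 1112 at an unadjusted p under 0.05 and 340 that also changed at least 2-fold, 178 higher and 162 lower. DESeq2 called 89, limma on log2(FPKM + 1) 0, limma voom 0, and edgeR on only the 6 samples compared 9. In that fit of 6 samples, 1923 of 13750 genes (13.99%) had an unadjusted p under 0.05. Without sham library 1 edgeR called 0, the 2 counts were 492 and 206, and DESeq2 called 7 genes, Ctgf (adjusted p = 0.00647), Dnajb4 (0.00426), Nr4a3 (0.00423), Fosl2 (0.00423), Adamts2 (0.0336), Thbs1 (0.0139) and Apold1 (0.00346). The number at an unadjusted p under 0.05 was 672 without sham library 3 and 1722 without library 1 of the single exposure, where the number with 2-fold change was 512. The groups did not overlap in 3078 genes (21.9%), where chance gives 10% for 3 against 3 libraries and 20% for 2 against 3.

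The contrast of 3 weekly exposures with a single exposure tests whether the irradiated groups differed. It does not use the sham values, although their spread enters the fit. Number of exposures, total dose and the weeks of treatment differ together between these groups, so their effects cannot be told apart. Type I interferon genes were lower after 3 exposures, with 27 of 28 members lower and a median of -0.55, although the list median of library 3 of the single exposure (0.29) lay below that of library 1 of the 3 exposures (0.42). They included Irf7 (-0.88 ± 0.26) and Ifit1 (-1.10 ± 0.35). Extracellular matrix genes were higher, with 25 of 30 members and a median of 0.22, including Eln (2.17 ± 0.51) and Mmp2 (0.72 ± 0.22), although here too library 3 of the single exposure (0.43) lay above library 2 of the 3 exposures (0.37) in the list median. All 29 heart muscle genes were lower, with a median of -4.61, but the list median per library was 4.21, -3.26 and -0.31 after a single exposure, so the excess lay in library 1, which held 5176 CPM of the cardiac gene Myh6. Oas3 had the smallest p of any gene, at 14.9 to 22.2 CPM after a single exposure, 5.59 to 6.28 CPM after 3 exposures and 6.25 to 7.73 CPM in sham, a log2 change of -1.66 ± 0.23 (SE, n = 3 against 3, edgeR adjusted p = 0.599).

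The camera adjusted p was 2.91e-11 for interferon genes, 0.000234 for matrix genes and 4.90e-13 for heart muscle, and these 3 lists of 22 were called without each library in turn, with largest adjusted p of 0.00739, 0.0418 and 0.0298. With an estimated correlation the adjusted p was 0.715 for each. Adjusted over the list alone, 1 interferon gene, 0 matrix genes and 26 heart muscle genes were called, and over all genes tested none. The other 19 lists lost the call without 1 or more libraries. For proliferation genes (median -0.37, adjusted p = 0.000125) the value was 0.351 without library 2 of the 3 exposures, and for lipid synthesis (median 0.29, 0.000664) it was 0.211 without library 3 of the 3 exposures. For skeletal muscle (median -2.29, 0.000464) it was 0.312 without library 1 of the single exposure. With an estimated correlation the adjusted p of each was 0.715.

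Several transcripts made chiefly in liver were among those with the smallest p. Alb, albumin (chromosome 5, 90460897 to 90476602), stood at 22.7 to 27.9 CPM after a single exposure, 0.175 to 1.09 CPM after 3 exposures and 0.394 to 7.05 CPM in sham. Serpina3k had 59 fragments after a single exposure and 0 after 3 exposures, at least 20.2-fold lower against a floor of 3 fragments over the group. Pzp stood at -3.50 ± 0.78, Ifitm6 at -2.35 ± 0.52, and the higher genes were Col16a1 (0.94 ± 0.18), Csad (0.89), Ogfod2 (1.02), Rps21 (0.65) and Inpp1 (0.81). Except for Oas3, their edgeR adjusted p was 0.753. edgeR called 0 genes, with 920 at an unadjusted p under 0.05 and 311 that also changed 2-fold, 66 higher and 245 lower. In a fit of only the 6 samples compared, 400 of 13798 genes (2.90%) had an unadjusted p under 0.05, where chance gives 689.9. DESeq2 called 5, limma on log2(FPKM + 1) 1 and limma voom 0. The number at an unadjusted p under 0.05 was 605 without sham library 1 and 1816 without library 3 of the single exposure, and the number with 2-fold change was 570 and 678 without libraries 2 and 3 of the single exposure. The groups did not overlap in 1120 genes (7.96%), below the 10% that chance gives.

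Over both irradiated groups against sham, 25 of 26 immediate early genes were lower (median -0.93), as were 40 of 48 ribosomal protein genes (-0.32), 22 of 23 platelet genes (-0.64) and 23 of 25 glucocorticoid-responsive genes (-0.71), and each list fell. Proliferation (0.77, 32 of 34) and interferon genes (0.52, 27 of 28) rose. The camera adjusted p was 3.63e-25, 2.01e-16, 8.14e-13, 2.93e-12, 3.61e-11 and 6.19e-09, and with an estimated correlation the adjusted p was 0.286, 0.286, 0.286, 0.340, 0.491 and 0.491. Adjusted over the list alone, 13 immediate early, 19 ribosomal, 5 platelet, 9 glucocorticoid-responsive, 0 proliferation and 2 interferon genes were called, and over all genes tested none. The medians of the first 3 lists per library were lower in all 6 irradiated libraries than in all 3 sham libraries. For immediate early genes the gap was narrow, from -0.31 to -0.27. The permutation p was 0.0119 for each of the 3 lists, the smallest that 84 splits can give, and 0.194 after adjustment over the 49 lists. Without sham library 1 it was 0.0357, the smallest that 28 splits can give, and 0.583 after adjustment. For the glucocorticoid-responsive, proliferation and interferon lists the libraries overlapped, with a permutation p of 0.0357, 0.0952 and 0.131, and of 0.107, 0.179 and 0.214 without sham library 1. These medians were taken relative to the mean of the real sham libraries before permuting. The permutation p-values are therefore not exact and may be too small. Heat shock genes fell by the test (adjusted p = 9.82e-06, 0.491 with an estimated correlation), with 5 called adjusted over the list alone, a mean of -0.47 and a median of 0.00.

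**Figure D3:**
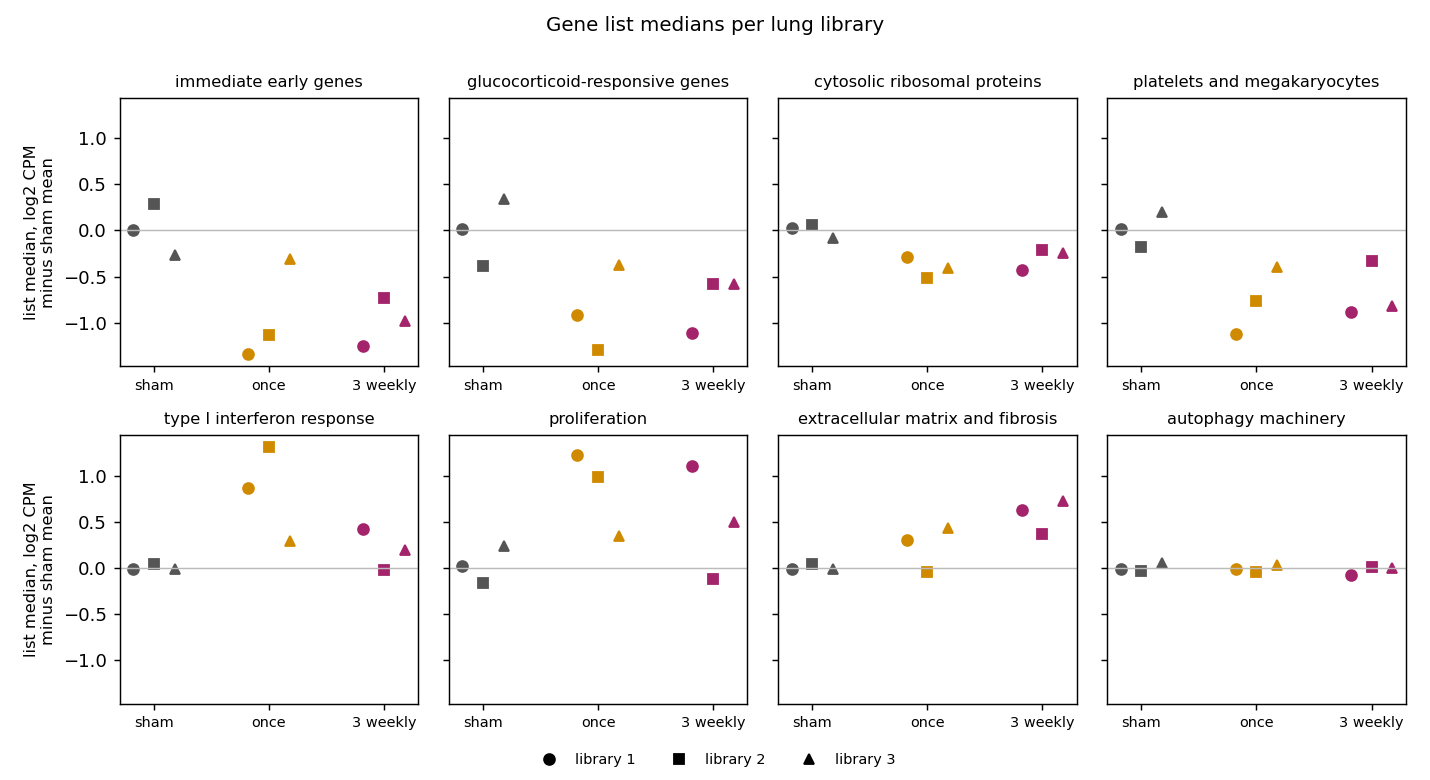
Median log2 difference from the sham mean over the measured genes of named lists, with 1 point per library. Immediate early genes lay at -1.34 to -0.31 in the irradiated libraries and at -0.27 to 0.28 in sham.

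edgeR called 0 genes over both irradiated groups and 0 by the F-test, with 1536 and 1370 at an unadjusted p under 0.05. The smallest adjusted p was 0.0715, for Crem. DESeq2 called 200 and 161, limma on log2(FPKM + 1) 0 and 1, and limma voom 0 and 0. Without sham library 1 the numbers at an unadjusted p under 0.05 were 635 and 604 and DESeq2 called 24 and 20, and without sham library 3 they were 837 and 767. Without library 1 of the single exposure edgeR called 29 genes over both groups, 3 higher and 26 lower, and without library 3 of the single exposure it called 9, all lower. The number at an unadjusted p under 0.05 by the F-test rose to 2067 without library 3 of the single exposure.

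None of the camera calls in any contrast held with an estimated correlation, and fry called 0 lists in each contrast. Its mixed test, which asks whether genes of a list change in either direction, called 9, 10, 1 and 11 lists for the single exposure, the 3 exposures, their difference and both groups, and 1, 0, 0 and 6 without sham library 1. Camera called 15, 25, 22 and 21 lists, of which 7, 12, 3 and 12 were called without each library in turn.

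The log2 changes after a single and after 3 exposures fitted by edgeR had a Pearson r of 0.50 across 14074 genes, which are not independent replicates. For differences of mean log2 CPM, the measure that was also simulated, r was 0.579, and unchanged groups simulated against the same sham libraries gave 0.122. The covariance was 0.142 against a simulated 0.0123, and 69.6% of genes changed in the same direction against a simulated 51.4%. The simulated groups were drawn around the observed sham means, so the sampling error of the sham libraries, which enters both real effects, was left out. The simulated values are therefore too low as a chance level, and part or all of the excess may come from the shared controls. The sham group is too small to be split, so these values do not show a shared response. Leaving out libraries gave a jackknife SD of r of 0.220.

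The lists of autophagy, the process that the reporter strain marks, were not called by camera in any contrast. The median of the 30 measured genes of the autophagy machinery was -0.01 after a single and -0.03 after 3 exposures, and that of the 26 autophagy receptors and regulators was 0.02 and 0.02. The mixed test of fry passed for the receptors and regulators over both groups (adjusted p = 0.0430, 0.549 without sham library 1). Adjusted over that list alone, 1 gene was called lower over both groups and 1 after a single exposure. Map1lc3b, which encodes the LC3B protein (chromosome 8, 121590361 to 121598760), stood at -0.06 ± 0.14 and -0.12 ± 0.14 (SE, n = 3 against 3), and the autophagy receptor gene Sqstm1 at -0.20 ± 0.15 and -0.19 ± 0.15. The mice carry LC3 fused to green fluorescent protein, and whether reads of that fusion enter the Map1lc3b value was not tested. Map1lc3a stood at 0.37 ± 0.44 and -0.08 ± 0.44, and Becn1 at -0.32 ± 0.13 and -0.16 ± 0.13. The p53 targets Cdkn1a (-0.37 ± 0.24) and Mdm2 (-0.21 ± 0.16) did not pass the test after a single exposure, and the p53 list was not called by camera, with a median of -0.07 after a single exposure (adjusted p = 0.244) and of -0.01 after 3 exposures (0.273). Its mixed test had an adjusted p of 0.0869 after a single and 0.0438 after 3 exposures and of 0.0186 over both groups, where 1 gene was called lower over the list alone. These were 0.721, 0.688 and 0.509 without sham library 1. Tgfb1 stood at 0.06 and 0.44, Fkbp5 at -0.35 and -0.36, Sftpc at 0.18 and 0.40, Scgb1a1 at -0.17 and -0.27, the globin gene Hbb-bs at -0.01 and 0.85, and the neutrophil gene S100a8 at -1.39 and -2.68 after 1 and 3 exposures. Myh6 stood at 3.10 ± 1.54 and -1.87 ± 1.48. The smallest edgeR adjusted p among these 13 genes over both contrasts was 0.380. Gdf15 and Il6 had 0 to 7 and 0 to 4 fragments per library, and a difference was not detectable at this depth.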

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

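Chosen only after the result was seen were the tests and simulated draws of sham library 1, the tests of the immediate early genes without sham library 1 and without library 1 of the single exposure, the test of the interferon genes without each library, and the splits for the F-test at an unadjusted p under 0.05. The tests with the clock genes or the immune lists as a covariate and the other counts over splits of the samples were written down before their results were seen.

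Sham library 1 lay so close to the average of sham libraries 2 and 3 that the number of independent sham lungs is in doubt. A separate lung of average profile was argued against, since the median squared deviation of 0.170 times the counting variance lay far below the lowest of the other 251 combinations of a library with 2 others, 0.762. An equal pool of both RNAs sequenced on its own was argued against as well, since the median lay at -0.285 from 0.455, the chi-square median for separately drawn reads. In 20 simulated draws of all 3 libraries this median was 0.439 to 0.482, and it was 0.277 to 0.305 where the counts of sham libraries 2 and 3 were taken as free of counting error. Reads drawn from the other libraries gave 0.112, so that 0.170 lay between shared and separate reads. The remaining deviation was 0.772 of the counting SD of sham library 1, between the simulated 0.627 for reads drawn from the other libraries and 0.984 for separate reads, which is consistent with shared reads. The design offers no biological explanation and none was tested. Among tested genes with a mean of at least 50 fragments in sham, 11 lay more than 10-fold above the mix. Of these, 8 were on the fixed skeletal muscle list, such as Ckm, with 2349 fragments against 44 and 10. The other 3, Trdn, Mylk4 and Lars2, were not on that list. Myh4, with 4995 fragments against 0 and 0, did not pass the filter on low counts and is not among the 11.

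Immediate early genes were lower in all 6 irradiated libraries than in sham. With the log2 difference of the clock genes Dbp and Arntl as a covariate, the median over both irradiated groups was -0.90, against -0.93 before, with an adjusted p of 6.32e-22. That difference was 1.04 to 1.64 in sham and -3.23 to 4.06 in the irradiated libraries. A linear term in it could hardly move the contrast and does not remove a cyclic effect, so time of day stays open. Heart tissue in library 1 of the single exposure was argued against, since without that library the adjusted p was 8.30e-20. These are camera values with a preset correlation, and with an estimated correlation the adjusted p was 0.286. Whether the call rests on counting sham library 1 as a further animal stays open, because leaving it out hardly moves the sham mean. Without it the permutation p of the list medians was 0.0357, the smallest that 28 splits can give, and 0.583 after adjustment. Those medians were taken relative to the sham mean before permuting, so this p is not exact. The mixed test of fry had an adjusted p of 0.0474 without sham library 1, against 0.00408 with it. Differences in handling between groups, such as the time from death to freezing, were not tested and stay open, as does an effect of brain irradiation.

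Interferon genes were higher after a single exposure and lower again after 3 exposures by the list test, with medians per library of 0.87, 1.31 and 0.29 and of 0.42, -0.03 and 0.19 that overlap. With the means of the lymphocyte and monocyte lists as a covariate, the median was 0.59, against 0.85 before. The camera adjusted p was 2.98e-07. That covariate was -0.19, 0.88 and 0.12 after a single exposure, -0.14 to 0.15 in sham and -0.02 to 0.06 after 3 exposures. Its term rests mainly on library 2 of the single exposure, so a larger share of lymphocytes and monocytes stays open. A single library was argued against, since the highest adjusted p without each single-exposure library was 1.18e-06. A response in the lung to brain exposure is a candidate explanation that was not tested against infection or cage effects. Adjusted p was 0.482 with an estimated correlation, so the call rests on a low assumed correlation between interferon genes.

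Lists were also noted where the camera direction against sham differed between the irradiated groups and their difference passed the camera test, which by itself does not show a difference from sham. TGF-beta pathway genes had medians of 0.06 after a single and 0.22 after 3 exposures, both above sham, and its camera direction was down in the first only at an adjusted p of 0.993. The adjusted p for the difference was 0.0385, 0.715 with an estimated correlation and 0.790 without 1 library. Nuclear genes of oxidative phosphorylation had medians of 0.24 and -0.20, with an adjusted p of 0.0174, 0.965 with an estimated correlation, and a turned direction without library 1 of the single exposure (6.9e-05). Endothelial genes had medians of -0.23 and 0.08, with an adjusted p of 0.000354, 0.715 with an estimated correlation, and a turned direction without library 1 of the single exposure (0.390). NK cell and cytotoxic genes had medians of 0.70 and -0.03, with an adjusted p of 3.43e-05, 0.715 with an estimated correlation and 0.902 without library 2 of the single exposure. Heart muscle genes had medians of 2.65 and -1.93, with an adjusted p of 4.90e-13 and 0.715 with an estimated correlation. The median per library was 4.21, -3.26 and -0.31 after a single exposure and -1.95, -2.67 and -1.11 after 3 exposures, so only library 1 of the single exposure lay above sham, and without it the adjusted p was 0.0298. Fatty acid oxidation genes had medians of 0.56 and -0.13, with an adjusted p of 4.36e-05, 0.715 with an estimated correlation and 0.479 without library 1 of the single exposure.

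For contrasts of 3 against 3 samples there are 10 splits, too few for a share under 0.05. For a single exposure against sham, 0 genes were called in the real split and at most 0 in the others, so that 10 of 10 splits were at least as large. The count at an unadjusted p under 0.05 with 2-fold change was 487 against at most 478 (1 of 10), and the number of lists 15 against at most 27 (10 of 10). For 3 exposures against sham the values were 0 against at most 0 genes (10 of 10), 340 against at most 121 (1 of 10) and 25 against at most 23 lists (1 of 10). For the difference of the irradiated groups they were 0 against at most 2 genes (10 of 10), 311 against at most 837 (9 of 10) and 22 against at most 26 lists (8 of 10). For both irradiated groups against sham chance cannot be excluded, with 349 genes against at most 737 with 2-fold change (23 of 84 splits) and 21 against at most 32 lists (48 of 84), beside 0 called genes against at most 2 (84 of 84). For the F-test it cannot be excluded either, with 1370 genes at an unadjusted p under 0.05 against at most 2699 over 100 drawn splits (7 of 100), and 0 called genes against at most 15 (100 of 100). Where the real count of called genes was 0, every split was at least as large by construction, so those comparisons decide nothing. For each irradiated group against sham, only the real split kept the 3 sham libraries together. If sham library 1 shares reads with the others, the spread of that split alone is too small and its counts may be too large. The splits with 837, 737 and 2699 genes each put library 1 of the single exposure with libraries 1 and 3 of the 3 exposures in 1 group, which points to a structure among these libraries whose source was not tested.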

How the results depend on the processing

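Chosen only after the data were seen were limma on log2(FPKM + 1), limma voom, robust moderation, counts as deposited, and the fits without sham library 1 by tools other than edgeR or without pairs of irradiated libraries; the other settings were planned. The counts of 0 genes by edgeR were also 0 with DESeq2's size factors, without a filter on low counts, with a mean FPKM of at least 1, with robust moderation, with counts as deposited, with limma voom and with the replicate block. Camera with a preset correlation called 15, 25, 22 and 21 lists for the single exposure, the 3 exposures, their difference and both groups, and between 13 and 29 lists per contrast over all its settings. The sham group is a limit, because the sham spread rests on libraries that may not be 3 independent lungs, and so is the correlation within lists, since no list was called once it was estimated. Depth of 4987856 to 7381021 fragments limits genes with few fragments, and in simulated libraries edgeR recovered 9 of 67 changes of 2-fold for the single exposure. DESeq2 could not be applied to the list tests, the 6-sample fits to the contrast of both irradiated groups or the F-test, and every other alternative in the plan was run. Unless stated, the cause of a difference was not tested.

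DESeq2 called 198, 89 and 5 genes for the single exposure, the 3 exposures and their difference, 200 over both irradiated groups and 161 by the F-test. Without sham library 1 it called 17, 7, 4, 24 and 20. Limma on log2(FPKM + 1) called 5, 0, 1, 0 and 1 genes, and without sham library 1 it called 0, 0, 2, 0 and 2. With a pseudocount of 0.5 limma called 4, 0, 1, 1 and 2, and with 0.1 it called 4, 1, 1, 1 and 2. With quantile normalization it called 4, 0, 1, 0 and 1, with median centring 4, 0, 1, 0 and 1, and without trend and robust moderation 4, 0, 3, 1 and 3. With array weights it called 1153, 539, 1, 3262 and 1878 genes, with a correlation between the 2 effects against sham of 0.751. Those weights did not converge and gave sham library 1 a weight of 631, so these calls were not used. A fit of only the 6 samples compared called 9 genes for the 3 exposures.

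The counts at an unadjusted p under 0.05 with at least 2-fold change were 487, 340, 311 and 349 for the single exposure, the 3 exposures, their difference and both groups. Without a filter on low counts, which tests more genes, they were 746, 512, 551 and 569. Limma on log2(FPKM + 1) gave 292, 203, 117 and 176, and without sham library 1 it gave 256, 161, 105 and 154. Quantile normalization gave 307, 201, 101 and 187, median centring 288, 197, 101 and 177, and the fit without trend and robust moderation 295, 204, 119 and 177. For the difference alone, the count was 181 with a pseudocount of 0.5, 120 with array weights, 159 with limma voom and 179 with only the 6 samples compared. Without library 1 of the single exposure and library 3 of the 3 exposures the counts for the 3 exposures and both groups were 569 and 542. Without library 1 of each irradiated group they were 559 and 547, and 25 genes were called over both groups.

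Whether replicate numbers pair the samples could not be decided. Of the 9 pairs with the same number, 4 correlated above 0.1, and 4 of the 9 libraries correlated best with their own number. The mean correlation was 0.060 for pairs with the same number and -0.031 for the others, with overlapping ranges of -0.079 to 0.304 and -0.384 to 0.242. With the replicate number as a block the count for the difference was 180, the numbers of called genes stayed at 0, and the numbers of lists were 16, 23, 23 and 21.

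Leaving out 1 library in turn, the counts with 2-fold change ranged from 282 to 928 for the single exposure, 206 to 512 for the 3 exposures, 259 to 678 for the difference and 208 to 507 for both groups. Genes called over both groups ranged from 0 to 29, and lists called for the difference from 14 to 25. The lowest counts for the contrasts with sham were those without sham library 1. Over all repeats of the called lists, 632 kept call and direction, 105 lost the call and 10 turned. For the single exposure, adjusted p ranged from 2.58e-05 to 0.279 for alveolar type 1 genes, 3.17e-05 to 0.0803 for endothelial genes, 2.58e-05 to 0.892 for B cells and 1.70e-06 to 0.361 for NK cells, with the highest value in the turned direction. It came without single-exposure library 2 for NK cells and without single-exposure library 1 for the others. For the difference, the turned values were 6.88e-05 for oxidative phosphorylation (range 5.97e-07 to 0.246), 0.390 for surfactant genes (from 1.10e-05), 0.390 for endothelial genes (from 1.70e-07), 0.375 for B cells (from 2.88e-05) and 0.0791 for neutrophils (range 6.01e-06 to 0.423). Over both groups, skeletal muscle ranged from 1.19e-14 to a turned 0.989 without sham library 1.

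Camera with an estimated correlation called 0, 0, 0 and 0 lists, and fry 0, 0, 0 and 0, in both cases also without sham library 1.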

Other observations

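The values below were looked up only after the data had been seen, apart from the list medians, and all tests here were chosen at that point. Adipocyte genes, which mark fat tissue, had a median of 2.39 log2 units above sham in library 1 of the single exposure and of 2.43 in library 3 of the 3 exposures, against -1.43 to -0.48 in the other irradiated libraries. Cyp2e1, which is expressed in fat as well as in liver, stood at 330 and 223 CPM in those libraries against 2.09 to 20.9 CPM elsewhere. Mesothelial genes, which mark the lung surface, had a median of 0.89 and 0.64 in the same libraries and of -1.48 in library 1 of the 3 exposures. Plasma cell genes varied less, with medians of -1.21 to 0.04 over the 9 libraries, and Igj, the immunoglobulin joining chain, stood at 23.6 CPM in library 3 of the single exposure and at 498 to 691 CPM in sham.

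Clock genes differed between libraries of the same group. Dbp, a transcription factor of the clock output, stood at 51.9, 10.5 and 79.6 CPM after a single exposure and at 3.32, 4.36 and 120 CPM after 3 exposures, against 36.4, 56.9 and 18.5 CPM in sham. Arntl, which encodes BMAL1, ran opposite in the irradiated groups, at 28.4, 30.5 and 5.43 CPM and at 31.4, 43.7 and 6.88 CPM, against 15.7, 18.1 and 8.86 CPM in sham.

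Of 17 genes expressed chiefly in liver, 8 were higher in all 3 libraries after a single exposure than in every sham library, most of them at low levels, and the other 9 overlapped sham. Ahsg stood at 3.03 to 12.1 CPM there, 0 to 2.40 CPM in sham and 0 to 0.873 CPM after 3 exposures, and Ttr at 0.479 to 1.21 CPM against 0 to 0.320 CPM in sham, whereas Fgb overlapped, at 0.798 to 1.06 CPM against 0 to 2.45 CPM in sham, and Hp, at 380 to 599 CPM against 516 to 641 CPM, did as well. The summed CPM of 17 liver genes was 974 to 1279 after a single exposure and 863 to 1058 in sham, with an exact permutation p of 0.4 (two-sided, smallest possible p 0.1), and this sum was dominated by Hp and Trf, which lung also expresses.

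Library 3 of the 3 exposures had 0 fragments of the Y-chromosome genes Ddx3y, Eif2s3y, Uty and Kdm5d. The other 8 libraries had 420 to 657, 334 to 564, 427 to 648 and 131 to 340 fragments of them. The labels used here do not give the sex of the mice, and no fit took it into account. These genes point to a library of another sex within the group of 3 exposures. Calls lost without that library, such as those of lysosome, heat shock and histone genes against sham, were not tested for this. The same holds for lipid synthesis against the single exposure.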
